A study of Bos taurus with 10 samples.

How the data were processed

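Blood RNA of 10 cattle pools was analysed from the authors' deposited gene tables, 1 per pool. The libraries were poly(A)-selected and stranded, per the labels' protocols, from column-purified total RNA. Per the submitters' processing notes, STAR 2.5.1b, HTSeq (version not given in the sources used here) and the genome build UMD3.1 were used. The role of each tool, the annotation release and any read filters are not given in the sources used here. The deposited values are whole-number read counts per Ensembl gene, not normalized, in 3 columns: without regard to strand and for each strand. The 4-column layout, with 4 rows for reads given to no gene, is that of STAR's gene counts.

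The labels name the libraries as stranded without naming the strand, so the strand column with the larger total was used, by a rule fixed beforehand. It held 97.61% of the counts of both strand columns. The 4 rows that name no gene stayed out of library sizes and tests. Together, reads that were unmapped, multimapping, in no gene or ambiguous made up 36.09 to 44.23% of the reads of a library, of which unmapped reads were 7.77 to 16.71%, reads in no gene 20.10 to 23.78% and multimapping reads 4.64 to 7.10%. Multimapping reads are not counted to genes, so that near-identical paralogs are under-counted. Depth was 24487010 to 32663198 counts per library. PCR reads without molecular identifiers are not independent molecules. Coordinates and gene structures were not used here.

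Pools were grouped by their titles, which gave 5 control and 5 supplemented pools. The average copper level of each pool was copied from the labels. The tests, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The reference table used here, of 37063 genes, holds 0 of the 24616 Ensembl identifiers, so the gene lists, the blood cell markers, the haemoglobin share and the alternatives that need them were not analysed here. The rule named up to 12 genes with a symbol per direction past the threshold, and, where none passed in a direction, the 5 with the smallest unadjusted p. None passed and no symbols were at hand, so the first 2 of the 5 in each direction are given by identifier. The parts of the rule that named copper genes, list members and markers by symbol could not be applied.

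Genes were kept with edgeR's filterByExpr (minimum count 10, by group), which left 12932; 6160 genes had no count in any library. Counts were scaled with TMM and tested with edgeR 4.0.16 (quasi-likelihood fit and F test, R 4.3.3), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The models were group, log2 copper, and both together. Standard errors were derived from the unshrunken coefficient and the F statistic, and 95% intervals from the t distribution with the test's degrees of freedom. CPM values are TMM-scaled, and log2 CPM for profile comparisons used a prior count of 2. Single values were compared by exact permutation (5 against 5, whose smallest two-sided p is 0.00794), and correlations by 100000 permutations. Alternatives were DESeq2 1.42.0 (Wald test, and its size factors within edgeR), limma 3.58.1 voom with sample quality weights, no filter, unstranded counts, 1 surrogate variable from sva 3.50.0, the replicate number as a block, copper on other scales, and leaving out each pool.

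The titles give both groups the numbers 1 to 5, but nothing says that a number pairs pools. No 2 pools of a group were the same library: the lowest chi-square per degree of freedom between counts was 22.75. The group test was tested on simulated data with 12932 genes, of which 200 were changed. It recovered 26% of genes changed 1.5-fold, 72% of those changed 2-fold and 96% of those changed 4-fold, with 7 false calls. For simulated slopes on copper it recovered 96% of genes changed 1.5-fold per doubling, which is a larger change over the whole range of copper, with 11 false calls. A second test thinned known changes into the real libraries on 10 splits that mixed the groups; there 438 further calls fell on genes that had not been thinned. Abundant genes, used to gauge reads on the wrong strand, had at least 5000 sense counts in every pool, and slopes of their log2 ratios were fitted by least squares.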

Results

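Poly(A) RNA from cattle blood was sequenced in 10 libraries, each made from blood pooled from 3 animals, so that 30 animals were sampled if none was used in more than 1 pool. Blood is a mixture of circulating cells, and each value is therefore an average over animals and over cell types. The pools fell into 5 controls and 5 from animals given a mineral supplement to raise copper. Copper, a trace metal used as a cofactor by enzymes such as cytochrome c oxidase and superoxide dismutase, was recorded as 1 average per pool, with no unit stated. The recorded copper level was 52.63 ± 30.06 (SD, n = 5) in control pools and 227.65 ± 106 (SD, n = 5) in supplemented pools. The controls ranged from 23.42 to 95.61 and the supplemented pools from 95.48 to 342.42, so the groups met at a single level. Counts on the transcribed strand summed to between 24487010 and 32663198 per library over 24616 Ensembl genes, and 12932 genes passed the filter on low counts. The files pair none of the gene identifiers with a symbol, so genes are given by identifier and no gene group, pathway or blood cell marker could be described. Nothing in the labels separates repeated blood draws from separate herds or days, and the p-values measure only the spread between these pools.

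The first comparison asked which transcripts differed in blood between supplemented and control animals. No gene passed an adjusted p of 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the smallest adjusted p was 1.00. DESeq2's Wald test on the same counts called 1 gene, ENSBTAG00000004895, and limma's voom called 0. In edgeR, 255 of the 12932 genes lay under an unadjusted p of 0.05, which is 1.97% of them, where evenly spread p-values would give 646.6. Of these, 140 were higher and 115 lower in the supplemented pools. With 1 pool left out, the count under an unadjusted p of 0.05 ranged from 187 (without control pool 1) to 432 (without control pool 4). The median log2 fold change over all genes was -0.01, and 53 genes had a fitted fold change above 2 in either direction.

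The precision of this comparison can be read from the intervals of single genes. The median standard error of a log2 fold change was 0.17. The 95% interval, not adjusted for the number of genes, excluded a change of 2-fold or more for 11650 genes (90.1%) and a change of 1.5-fold or more for 8485 genes (65.6%). Known changes were also thinned into the real libraries, on splits that mixed the groups. There the same test called 28.6% of genes changed 1.5-fold, 68.8% of those changed 2-fold and 93.4% of those changed 4-fold. A call in either direction was counted. Those splits also held 438 calls on genes that had not been thinned, and further calls ease the adjusted threshold, so these shares apply to such splits and not directly to the real one.

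The 2 genes with the smallest unadjusted p in each direction are given as measurements that did not pass the adjusted threshold. ENSBTAG00000004895 had 16.1 ± 0.98 CPM (counts scaled to library size) in control pools and 8.71 ± 2.13 CPM in supplemented pools (SD, n = 5 each). Its log2 fold change was -0.88 with a standard error of 0.17, and every supplemented pool lay below every control pool (5.70 to 10.92 against 15.16 to 17.38 CPM). Its adjusted p was 1.00 in edgeR and 0.00273 in DESeq2, with a DESeq2 log2 fold change of -0.89. Over the 18 alternatives that recorded this gene the adjusted p ranged from 0.00273 to 1.00 (edgeR, DESeq2 and limma). ENSBTAG00000010828 had 63.3 ± 23.4 CPM in controls and 32.4 ± 8.23 CPM in supplemented pools, a log2 fold change of -0.97 ± 0.23 (SE), and its groups overlapped. ENSBTAG00000013407 had 9.61 ± 0.56 CPM in controls and 13.8 ± 1.62 CPM in supplemented pools, a log2 fold change of 0.52 ± 0.13 (SE), with no overlap between the groups. ENSBTAG00000033565 had 78.2 ± 7.70 CPM in controls and 106 ± 12.8 CPM in supplemented pools, a log2 fold change of 0.44 ± 0.11 (SE). The lowest supplemented pool for this gene, at 88.4 CPM, lay below the highest control, at 89.3 CPM. Over all tested genes, 36 had groups that did not overlap, 23 of them higher and 13 lower in supplemented pools, which is 0.278% against the 0.794% (102.6 genes) that chance gives for 5 pools against 5.

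**Figure D1:**
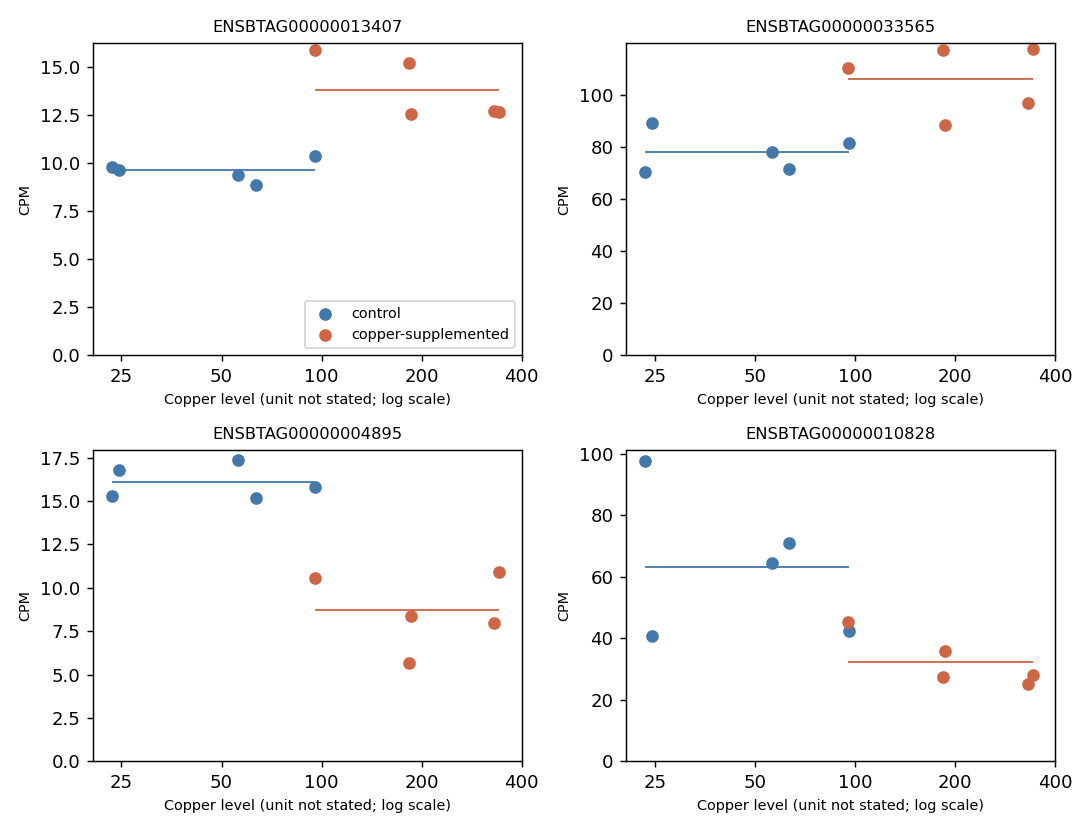
CPM, counts scaled to library size (vertical axis, linear from 0) against the recorded copper level (horizontal axis, log scale, unit not stated) for the 4 genes with the smallest unadjusted p between the groups. Each point is 1 pool and each horizontal line a group mean; for ENSBTAG00000004895 the supplemented pools lie between 5.70 and 10.92 CPM and the controls between 15.16 and 17.38 CPM.

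The second comparison asked which transcripts followed the copper level itself over all 10 pools. No gene passed an adjusted p of 0.05 for a slope on log2 copper (edgeR's quasi-likelihood test), and the smallest adjusted p was 0.947. Under an unadjusted p of 0.05 there were 344 genes (2.66%), 155 with a positive and 189 with a negative slope. DESeq2's Wald test called 7 genes, 2 that rose and 5 that fell with copper, and limma's voom called 0. When the copper levels were reassigned among pools, 10 of 40 assignments, the real one included, gave DESeq2 7 or more genes. In edgeR, the count under an unadjusted p of 0.05 ranged from 206 (without control pool 1) to 455 (without control pool 4) when 1 pool was left out. The median standard error of a slope was 0.06 log2 units per doubling of copper, and the 95% interval excluded a 1.5-fold change per doubling for 12651 genes (97.8%). A change per doubling adds up over the range of copper, 23.42 to 342.42. This share is therefore not comparable with the 65.6% given for 1.5-fold between the groups. Group and copper level were tied to each other by design, so the first and second comparisons are 2 readings of the same libraries. Of the genes under an unadjusted p of 0.05, 137 were shared, all in the same direction.

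ENSBTAG00000010828 fell by 0.41 log2 units per doubling of copper (SE 0.08) in DESeq2's test, at an adjusted p of 0.00668. In edgeR its slope was -0.41 with a standard error of 0.08 and its adjusted p was 0.947. ENSBTAG00000007191, at 429 ± 110 CPM in controls and 282 ± 63.1 CPM in supplemented pools (SD, n = 5 each), had a slope of -0.27 ± 0.06 (SE) in edgeR. ENSBTAG00000018941 was a low-abundance gene, at 1.65 ± 0.83 CPM in controls and 5.18 ± 3.21 CPM in supplemented pools, with a slope of 0.67 ± 0.14 (SE). ENSBTAG00000012030 had 43.1 ± 7.89 CPM in controls and 72.7 ± 20.9 CPM in supplemented pools, with a slope of 0.31 ± 0.06 (SE). These last 3 genes also had an edgeR adjusted p of 0.947, while DESeq2 gave adjusted p-values of 0.0175 for ENSBTAG00000007191, 0.0175 for ENSBTAG00000018941 and 0.0214 for ENSBTAG00000012030. Over the 18 alternatives that recorded their slopes, the adjusted p of each of these 4 genes reached 1.00 at its highest (edgeR). Its lowest was that of DESeq2, or for ENSBTAG00000010828 that without control pool 2. The edgeR count of 0 became 1 when control pool 2 was left out, through ENSBTAG00000010828 at an adjusted p of 0.00323.

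**Figure D2:**
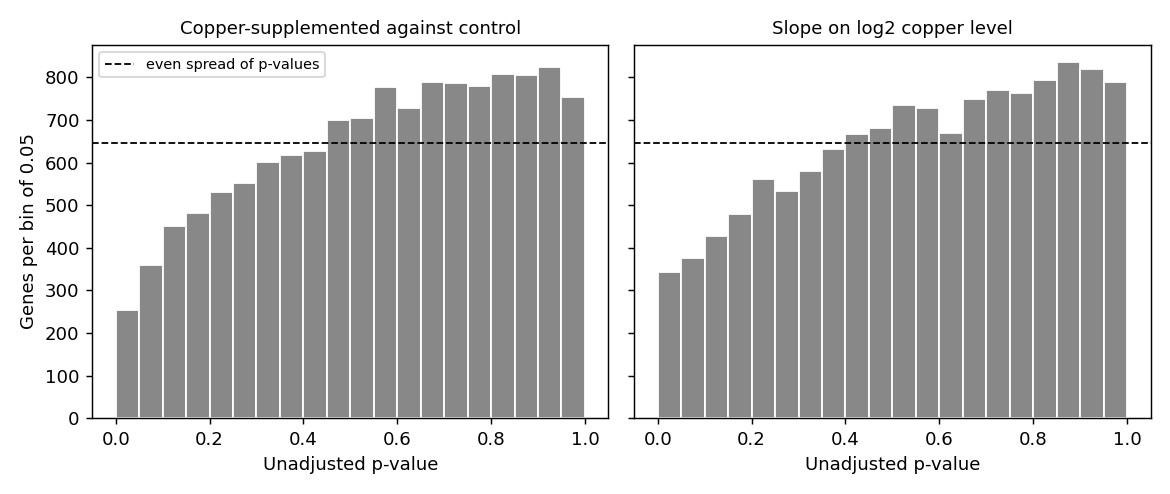
Number of genes (vertical axis) per 0.05 bin of unadjusted edgeR p-value (horizontal axis) for the group comparison and for the slope on log2 copper. The dashed line is an even spread of 646.6 genes per bin; the lowest bin holds 255 genes in the group comparison and 344 for the slope.

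The third comparison put group and log2 copper in 1 model, to ask for a copper slope within the groups and for a group difference at a given copper level. No gene passed for either term (edgeR's quasi-likelihood test). For the slope, 205 genes lay under an unadjusted p of 0.05 in edgeR. Leaving out 1 pool gave 160 (without control pool 5) to 353 (without supplemented pool 1). DESeq2 called 1 gene for the slope, ENSBTAG00000002096, named here after its values were seen. Its slope within the groups in DESeq2 was -0.36 with a standard error of 0.07, at an adjusted p of 0.00703, against 1.00 in edgeR. For the group term, 170 genes lay under an unadjusted p of 0.05 in edgeR, and DESeq2 called 0. With 1 pool left out, the edgeR count for the group term ranged from 140 (without control pool 5) to 336 (without supplemented pool 1). Since the groups met at 1 copper level only, the group term was imprecise, with a median standard error of 0.30 log2 units. The interval of the group term excluded a 2-fold change for 61.8% of genes. At the shared level, control pool 5 and supplemented pool 1 had copper of 95.61 and 95.48. With 1 pool on each side there is no test of this pair. Between them 3.22% of genes differed by more than 2-fold, against 3.02% between supplemented pools 1 and 2 and 13.8% between control pools 3 and 4.

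Whole profiles were then compared, by tests chosen after the pools had been plotted. The mean distance between pools of different groups was 0.013 log2 units (root mean square over genes) smaller than between pools of the same group, and 96 of the 126 splits into 5 and 5 gave a difference at least as large (exact permutation test, one-sided p = 0.762). The 5 pairs of pools with near-equal copper were 0.526 log2 units apart on average, against 0.518 over all pairs of pools (exact permutation test over 945 pairings, one-sided p = 0.602). Distance between profiles did not rise with the difference in log2 copper (r = -0.04, permutation test, one-sided p = 0.587). The first principal component held 33.5% of the variance between pools. Its scores averaged 0.27 ± 29.5 in controls and -0.27 ± 21.5 in supplemented pools (SD, n = 5 each, exact permutation test, two-sided p = 0.984). Control pools 4 and 5 and supplemented pools 1 and 2 had scores of 13.37 to 42.07, and the other 6 pools had scores of -30.78 to -3.15. Over all 10 pools its Pearson's r with log2 copper was 0.08 (permutation p = 0.814, adjusted over 10 library measures 0.903) and Spearman's rho was 0.20 (permutation p = 0.585, adjusted 0.731). Without the 2 pools farthest from the median copper level r was -0.25. For the second component, r with log2 copper was 0.22 (permutation p = 0.542, adjusted 0.848) and rho was 0.22 (permutation p = 0.537, adjusted 0.731), and without the same 2 pools r was 0.77, a value that was not tested.

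**Figure D3:**
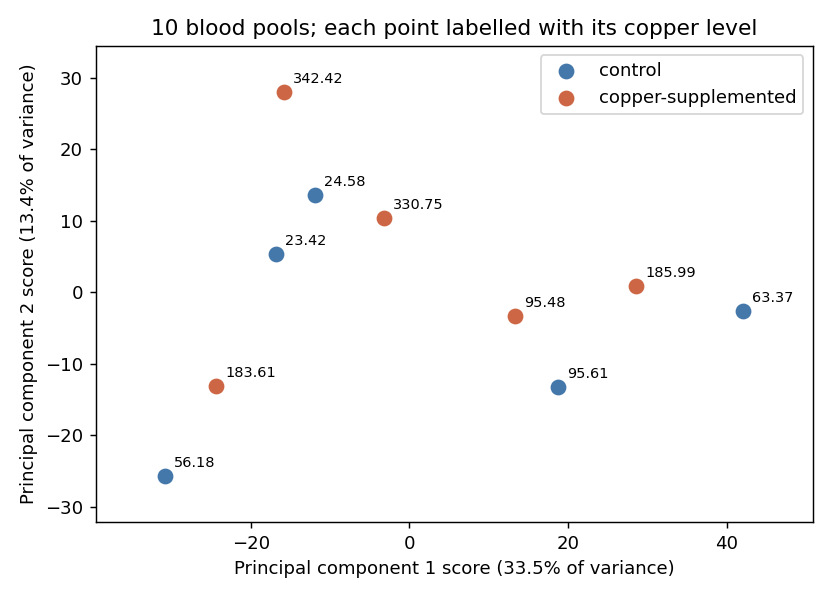
Scores of the 10 pools on the first and second principal components of log2 CPM (axes, with the percent of variance on each), coloured by group and labelled with the recorded copper level. Along the first component, which holds 33.5% of the variance, control and supplemented pools are mixed at both ends.

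For 8 measures of the libraries themselves, the difference between the groups was within the spread of the pools by exact permutation tests (two-sided, smallest p = 0.214, all adjusted p = 0.984, Benjamini-Hochberg over these and the first 2 components). Unmapped reads made up 11.1 ± 3.47% of reads in controls and 10.5 ± 1.95% in supplemented pools. Reads placed in no annotated gene made up 21.8 ± 1.26% and 22.5 ± 1.17%. Among the reads counted on either strand of a gene, the share on the strand opposite to the annotation was 2.5 ± 0.32% in controls and 2.27 ± 0.12% in supplemented pools (SD, n = 5 each).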

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

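All tests and alternatives for the opposite-strand counts were chosen after the 3 genes below were seen; for the scaling and the reassigned copper levels, the bounds were set before the outcome was seen, but the scaling was read apart for the genes that rose and the gene that fell only afterwards. Among the libraries, 1 value stood apart from its group. Supplemented pool 3 had counts for 15775 genes, where the other 4 supplemented pools had 15910 to 15936. It was 1 such value in 36 groups of values tested, and chance alone sets apart about 5% of groups.

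The strand opposite to the annotation, which the comparisons in the report do not use, held a signal tied to copper in 3 genes of 6021 tested (edgeR's quasi-likelihood slope on log2 copper, Benjamini-Hochberg threshold 0.05), with 380 genes under an unadjusted p of 0.05. Adjusted over both strands together, 0 genes passed, and the edgeR adjusted p-values of the 3 were 0.0946 for ENSBTAG00000007191 and 0.142 for the others. For supplemented against control pools the same counts gave 0 genes, with 322 under an unadjusted p of 0.05. The 3 genes are named here after their values were seen. ENSBTAG00000003963 rose by 0.34 log2 units per doubling of copper (SE 0.06, edgeR adjusted p = 0.045), from 359 ± 120 opposite-strand counts in controls to 518 ± 67.7 in supplemented pools (SD, n = 5 each). ENSBTAG00000045105 rose by 0.48 (SE 0.09, edgeR adjusted p = 0.045), from 26.4 ± 10.6 to 42 ± 13.5 counts. ENSBTAG00000007191 fell by 0.42 (SE 0.07, edgeR adjusted p = 0.0301), from 154 ± 66.8 to 68 ± 23.2 counts, and its sense counts had a slope of -0.27. Over all alternatives the smallest adjusted p ranged from 0.000731 to 0.61 (edgeR and DESeq2). The count of 3 became 0 without control pool 1, control pool 2, or supplemented pools 1, 2 or 5, 1 without control pool 3 or supplemented pool 4, 2 without supplemented pool 3 and 4 without control pool 4.

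Imperfect strand marking, which puts a small share of a sense transcript on the other strand, is argued against for the 2 genes that rose, since all 20 values (2 genes in 10 pools) had more opposite-strand than sense counts; ENSBTAG00000045105 had 0 sense counts in each pool. For ENSBTAG00000007191 leaked reads may account for the fall but this cannot be told apart: the opposite-strand count was 0.69% to 1.77% of the sense count, in every pool below the median share of 700 abundant genes, yet a leak in step with that median would hold the gene's share level relative to it, and the share relative to the median had a log2 slope of -0.13 (SE 0.05) per doubling of copper. That slope passed the bound set for it, of 2 SE, which does not exclude a leak, since 74 of the 700 genes (10.6%) passed it too, 9 had a slope as low, and this gene was picked for its slope. Chance assignment of copper levels gave as many genes in 4 of 100 reassignments, the real one included, with at most 5 genes in another. This share is under 0.05 for the count adjusted over the opposite strand alone. The reassignment was chosen after that count was seen, and 0 genes passed when adjusted over both strands, so chance is not excluded. The fall of ENSBTAG00000007191 was not reduced with the sense library sizes as the scale. Its slope was then -0.52 ± 0.09 (SE), 1.23 of its size before, with an edgeR adjusted p of 0.00342. The change of scale moved the slopes of all 3 genes downward, so the gene that fell had to gain. Neither the gain in slope nor that adjusted p is shown to be particular to this gene. With that scale 705 genes lay under an unadjusted p of 0.05 in edgeR, against 380 before. The median share of the 700 abundant genes also fell, with a log2 slope of -0.11 (SE 0.05) per doubling of copper. For ENSBTAG00000003963 and ENSBTAG00000045105 the scaling stays open, as does transcription tied to copper. Their slopes became 0.26 ± 0.07 and 0.39 ± 0.10 (SE), with edgeR adjusted p-values of 0.378 and 0.368. They kept 0.769 and 0.816 of their size, which met the preset 0.75. The margin of the smaller was below its error, a requirement added after the outcome was seen. Which transcripts these reads come from was not tested, since coordinates and gene structures were not used.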

How the results depend on the processing

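The first principal component as covariate and the opposite-strand alternatives were chosen after seeing the data; the others were planned. Over the 4 gene comparisons, 65 of 69 alternatives gave 0 genes. DESeq2's Wald test gave 1 gene between the groups, 7 for log2 copper and 1 for log2 copper with group as covariate; the cause was not tested. Leaving out 1 pool gave 0 genes throughout between the groups, for copper with group as covariate and for the group at a given copper level, and 0 to 1 for log2 copper, the 1 being ENSBTAG00000010828 without control pool 2. With the replicate number as a replicate block, 0 genes passed between the groups (254 under an unadjusted p of 0.05) and 0 for log2 copper (226). Across genes, which are not independent, same-numbered pools had deviations correlated at -0.28 to 0.42, only number 3 matched itself best, and the numbers were not taken as pairs. Under an unadjusted p of 0.05, the count between the groups ranged from 98 (a fold change tested against 1.2) to 592 (1 surrogate variable). That for log2 copper ranged from 206 (without control pool 1) to 794 (no filter, with 18456 genes tested in place of 12932). With the first principal component as covariate these counts were 586 and 691. Each log2 fold change and slope of the 7 genes named for the first 2 comparisons kept its sign under the 18 alternatives that recorded it. These genes were picked for a small p in the same pools, so a kept sign is no test. The log2 fold change of ENSBTAG00000004895 ranged from -0.98 to -0.76, with edgeR, DESeq2 and limma adjusted p from 0.00273 to 1.00. The 3 opposite-strand genes associated with copper became 1 with sense-strand library sizes, 0 when adjusted over both strands (smallest edgeR adjusted p 0.0946), 4 with DESeq2, and 0 to 4 when 1 pool was left out: 0 in 5 of 10 such settings. The gene lists, the removal of haemoglobin genes, the cell mixture covariate and the marker levels were not run, since no identifier could be matched to a symbol. Of 24616 genes, 6160 had no count in any library and 12932 passed the filter; whether more depth would bring in others was not tested.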

Other observations

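The tests of the group on the first component and of chance in the edgeR counts on the annotated strand, and the fit with the first component as covariate, were chosen after the result was seen; the bounds of the other tests were set before their outcome was seen. The first principal component had a Pearson's r above 0.8 in size with 2797 of the 12932 genes (21.6%), 1560 of them positive and 1237 negative. These genes define the component, so the count describes its breadth and is no test. Pools at its ends differed widely: control pools 3 and 4, with copper of 56.18 and 63.37, differed by more than 2-fold in 13.8% of genes, the most of any pair of pools. Of 8 library measures, the number of genes detected had r = 0.61 with the score (permutation p = 0.051, adjusted 0.135) and rho = 0.77 (permutation p = 0.013, adjusted 0.103), and r was 0.85 without the 2 pools farthest from the median score. The share of counts in the 10 most abundant genes had r = -0.71 (permutation p = 0.022, adjusted 0.131) and rho = -0.71 (permutation p = 0.026, adjusted 0.103), and r was -0.46 without those pools. Neither was tested as a source of the axis.

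The copper supplement is argued against as the source of this axis, since 0.0132% of the variance of its scores lay between the groups. After thinning every library to the smallest total, 20 times, the component still held at least 33.3% of the variance, against 33.5% before. Its scores correlated with the original ones at 1.00. This argues against unequal counting noise as the source, but thinning leaves in place any library trait that goes with depth. Depth itself had Pearson's r = 0.46 with the score (permutation p = 0.179, adjusted 0.287), and r was 0.71 without the 2 pools farthest from the median score. The share of reads in no annotated gene had Pearson's r = 0.68 with the score (permutation p = 0.033, Benjamini-Hochberg adjusted over 8 library measures 0.131; Spearman's rho = 0.649, permutation p = 0.050, adjusted 0.134). Without the 2 pools farthest from the median score r was 0.39. Those pools have the highest scores, and leaving them out narrows the range of the score, which can itself lower r. The drop therefore does not decide whether the relation rests on them. Spearman's rho lies between the preset bounds of 0.8 and 0.3: this explanation cannot be told apart from others with 10 pools. No further biological explanation was tested, since blood cell markers could not be matched to identifiers.

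Fewer genes lay under an unadjusted p of 0.05 than even p-values give (255 against 646.6), and a candidate explanation is that the axis inflates the spread within both groups while its scores are balanced between them. Over the 99 other splits of the pools, the count rose with the difference of mean scores between the arms (Spearman's rho = 0.804). The splits share libraries and are not independent. The component was computed from these libraries, and 21.6% of genes had r above 0.8 in size with it. A split that separates its scores must therefore give more small p-values, so this rise cannot decide whether the explanation holds. The split with most calls gave 2000 genes at an edgeR adjusted p of 0.05, with a score difference of 39.9 against 0.53 for the real split. For the same reason that split is no separate evidence. Another split gave 12 genes at a score difference of 1.61. Simulated unchanged counts, drawn as independent genes from the fitted dispersions, put 4.90% of genes under an unadjusted p of 0.05. This argues against a test that is too strict for independent genes, and does not cover genes that vary together. Over the other splits of the real libraries the median count was 383, also under 646.6. With the first component as covariate the count for the real split was 586, still with 0 genes called.

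Chance could not be excluded for the 3 counts above 0 on the annotated strand that were set against other splits. Between the groups, 73 of 100 splits gave as many as the real 255 genes under an unadjusted p of 0.05 in edgeR (highest other 4410). For log2 copper, 50 of 100 reassignments gave as many as 344 (highest other 3872). The 7 genes that DESeq2 called for log2 copper were matched or exceeded in 10 of 40 reassignments (highest other 1846). A called count of 0 in edgeR is met by every split by construction, so the comparison with other splits says nothing about chance there. This holds for the groups (100 of 100 splits, highest other 2000), log2 copper (100 of 100, highest other 916), copper within groups (30 of 30, highest other 3855) and the group at a given copper level (30 of 30, highest other 1657).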
